A study of Mus musculus with 8 samples.

How the data were processed

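RNA-seq was measured in 8 libraries of mouse embryoid bodies at day 9, with total RNA extracted with Trizol and RNeasy columns and Illumina TruSeq libraries, per the labels' protocols. Samples were grouped by their titles into the Prdm16 control, Prdm16 knockout, PR domain control and PR domain knockout, with 2 libraries each, and replicate numbers came from the titles. The submitters' processing notes name TopHat2 2.1.1, SAMtools 1.5, Cufflinks 2.2.1 and deepTools and the mm10 build, with no role or order for each. The gene annotation release and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes cannot be separated.

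The deposited table holds signal values, fragments per locus that the authors had divided by 1 size factor per library, per the file headers and the values, in the form Cuffnorm writes. Within a library the values were whole multiples of 1 step, between 0.827 and 1.24, and 99.99 to 100.0% of values were whole fragments within a tolerance of 0.1 once divided by it. Recovered fragments on named loci came to 6273789 to 9086885 per library. The authors also deposited FPKM values, which scale fragments by transcript length and library size, and these entered alternatives only. Their ratio to the fragments of a locus varied between libraries of like size. Prdm16 had 44 and 22 fragments in PR domain control replicates 1 and 2, at FPKM values of 1.03 and 1.15. Of 55020 table lines, 53068 distinct loci remained, of which 787 had no gene name. These held 1.88 to 2.53% of the fragments and stayed out of the tests. Of 52281 named loci, 1390 carried 2 or more gene names and 430 carried 2 or more protein-coding names, so that the value of such a locus belongs to no single gene. Of 53680 distinct names, 52644 were found in GENCODE M21 (GRCm38), from which coordinates, gene types and identifiers were taken.

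The test fixed before the data were examined was edgeR's quasi-likelihood test on raw counts. Since the deposited values were normalised, the main test was limma-trend on log2(value + 1) with the authors' scaling, and edgeR on the recovered fragments was an added alternative that called 6471 loci in the Prdm16 knockout and 3426 in the PR domain knockout. Loci with a value of at least 10 in at least 2 libraries were kept, 16623 in all. A model of the 4 group means was fitted to all 8 libraries, which left 4 residual degrees of freedom and 25.4 prior degrees of freedom. The contrasts were each knockout against its own control, the difference of these, and the PR domain control against the Prdm16 control. Benjamini-Hochberg adjusted p below 0.05 counted as a call. Overlap of calls was tested with Fisher's exact test, one-sided, per direction.

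Of 39 gene lists fixed before the libraries were read, 35 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over lists, with an estimated correlation and fry beside it. Mitochondrially encoded genes (0 tested members), skeletal muscle (4), genes of the two-cell-like state (1) and Y-linked genes (4) were not tested as lists. Each listed gene counted once, at the locus with the highest mean. Named genes followed a rule fixed with the lists. It took Prdm16 and Mecom. It took the 10 largest rises and falls per knockout among called loci with a mean CPM of at least 5, a gene symbol that is no predicted model and both knockout libraries on the same side of both controls. It took up to 4 members with the smallest adjusted p from each list that passed, and the 5 largest per direction for the other comparisons, with the Y-linked genes and Xist. The rule named 87 genes for the Prdm16 knockout and 104 for the PR domain knockout, of which the text prints a part. Other genes named meet the rule for at least 1 comparison, except Grb10's neighbours, which were chosen after their values were seen.

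The scripts were tested on simulated data with known changes for the Prdm16 knockout comparison over 16623 loci. Limma recovered 20 of 50 loci changed 1.25-fold, 37 of 50 changed 1.5-fold, 45 of 50 changed 2-fold and 49 of 49 changed 4-fold. It called 17 of 16399 unchanged loci. The simulation gave every locus the same spread between replicates and control sets that did not differ. It also changed far fewer loci than were called in the data, so these rates need not hold for the data. Intervals for ratios of fragments are exact at 95%, and a count of 0 was set to a floor of 3 fragments over the group. Both cover counting error only, since fragments without molecular identifiers are not independent molecules. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.63 and 2.40 in the Prdm16 control and knockout and 1.43 and 2.12 in the PR domain control and knockout.

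Alternatives were fitted beside the main test. They were DESeq2, total-fragment and upper-quartile scaling, the DESeq2 Wald test and limma-voom. Others were limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and log2(FPKM + 1) with no filter. Further ones were no filter on low values, a CPM filter, only the libraries compared, replicate blocks and each library left out. The last were the 20 most abundant loci left out of scaling and a minimum fold of 1.5. The CPM filter asked for at least 1 CPM in both libraries of a group. It kept 16808 loci, more than the main filter. Some changed more than 1 choice: the FPKM settings also changed the filter on low values, and the DESeq2 Wald test, limma-voom and edgeR used their own scaling. Leaving out a library leaves its group with 1 library, assumed to vary like the other groups. Added after the data were seen were edgeR and TMM scaling on recovered fragments, pseudocounts of 0.5 and 5, a run without chromosomes 8, 19 and Y, and a crossed pairing. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.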

Results

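The samples were embryoid bodies, aggregates in which mouse embryonic stem cells differentiate into derivatives of the germ layers, collected on day 9 on a C57BL/6 background. Prdm16 encodes a zinc finger transcription factor whose N-terminal PR domain is related to the catalytic domain of histone methyltransferases. RNA-seq was done on 8 libraries in 4 groups of 2: a Prdm16 knockout with its own wild-type control set, and a knockout of the PR domain, which the labels place at exon 4, with a separate wild-type control set. The libraries held between 6273789 fragments (Prdm16 knockout replicate 1) and 9086885 fragments (PR domain knockout replicate 2) on named loci. The other totals were 7138747 and 8142365 for the Prdm16 control, 7138382 for Prdm16 knockout replicate 2, 7588410 and 7417089 for the PR domain control, and 8463055 for PR domain knockout replicate 1. Levels are fragments per locus divided by the size factor of the library (normalised fragments), given as mean ± SD with n = 2. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, given ± SE from limma with Benjamini-Hochberg adjusted p over 16623 loci. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Nor do they say whether knockout and control differ in cell clone or line. Knockout and clone can therefore not be separated for any gene or list below. The wild-type sets alone differed at 5481 loci, against 6502 called in the Prdm16 knockout and 3190 in the PR domain knockout.

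Prdm16 itself (ENSMUSG00000039410.16, protein-coding, chromosome 4, 154316125 to 154636873, minus strand) was a low gene in every library. Positions here and elsewhere are GRCm38 from GENCODE M21. It had 24.4 and 26.3 normalised fragments in the Prdm16 control libraries and 11.2 and 1.10 in the knockout libraries, from 23, 28, 9 and 1 fragments. It fell in the Prdm16 knockout, with a log2 fold change of -2.38 ± 0.50 (limma adjusted p = 0.000306). The knockout held 22.3% of the control level (95% exact interval 10.1 to 44.5%, counting error only). The PR domain control libraries had 44.6 and 22.7 and the PR domain knockout libraries 23.3 and 15.7 normalised fragments. The log2 fold change was -0.71 ± 0.50 and did not pass (limma adjusted p = 0.377), and the knockout held 58.3% of control (95% exact interval 39.0 to 86.4%). It was -1.18 without PR domain control replicate 2 and -0.23 without PR domain control replicate 1. The fold changes of both knockouts differed by -1.68 ± 0.71, which did not pass either (limma adjusted p = 0.107). Fragments per gene do not show the loss of 1 exon, and the part of the gene removed in the Prdm16 knockout is not given in the sources used here. The value in the Prdm16 knockout depended on single libraries, at -1.11 without knockout replicate 2 and -3.65 without knockout replicate 1, and on log2(FPKM + 1) it was -0.69 and did not pass. The paralogue Mecom (chromosome 3, 29951296 to 30548008), which encodes another PR domain zinc finger protein, had a log2 fold change of -0.19 ± 0.09 in the Prdm16 knockout (limma adjusted p = 0.0921) and fell by 0.83 on the log2 scale in the PR domain knockout, from 499 ± 50.2 to 279 ± 13.0 (limma adjusted p = 2.43e-08).

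**Figure D1:**
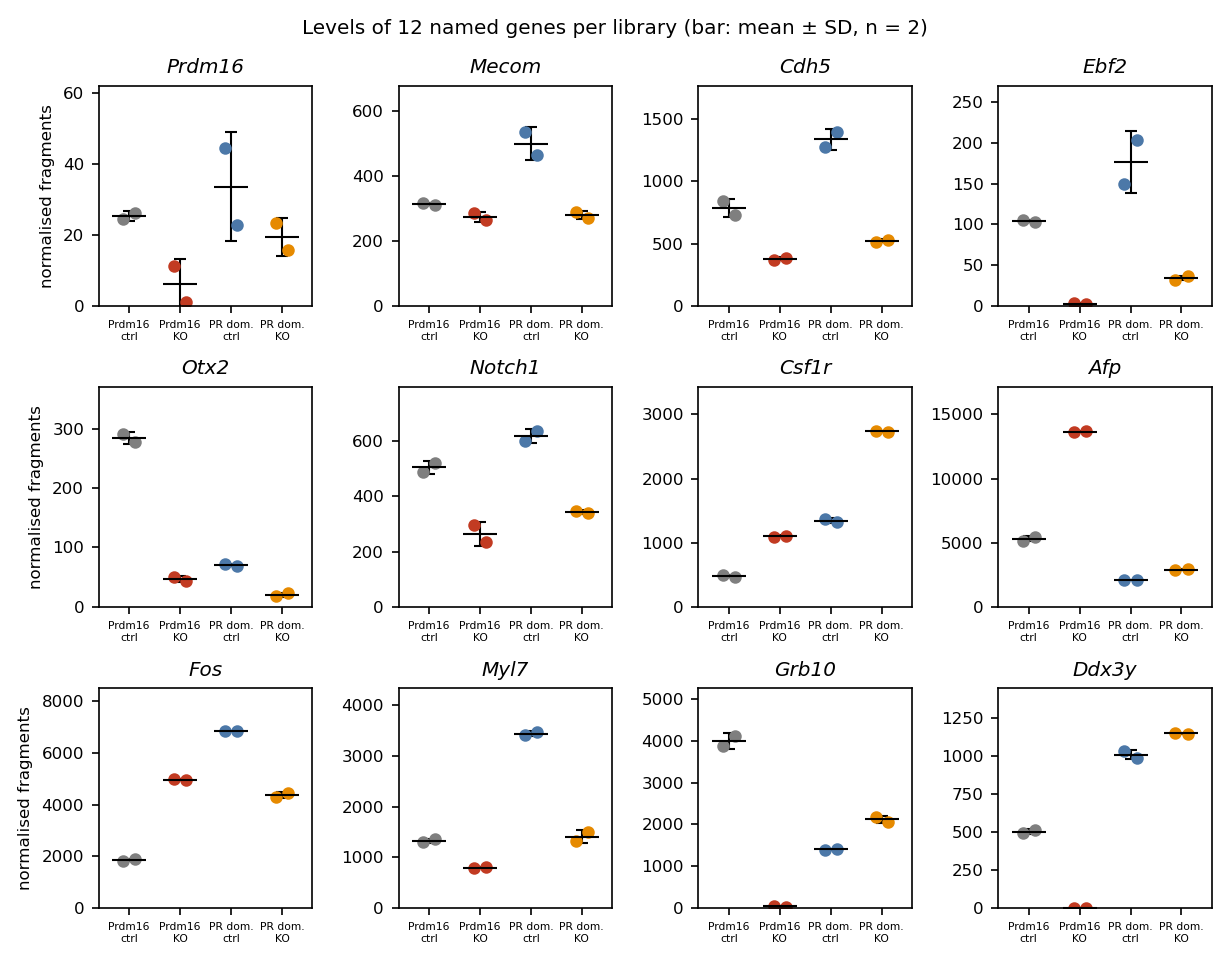
Normalised fragments of 12 named genes in each library (points) with the mean ± SD of each group (bars, n = 2), with each vertical axis starting at 0. Ebf2 and Cdh5 were lower and Csf1r higher in each knockout than in its control, Fos was higher in the Prdm16 knockout and lower in the PR domain knockout, and Grb10 and Ddx3y were near 0 in the Prdm16 knockout libraries only.

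The first comparison asked which genes differed between the Prdm16 knockout and its control set. Neural progenitor and early epiblast genes fell in the Prdm16 knockout, while immediate early, macrophage and endoderm genes rose. Among neural progenitor genes 15 of 19 tested members fell and 1 rose, with the same counts adjusted over the list alone. The median log2 fold change was -1.74 (camera adjusted p = 2.27e-05). They included Sox21, a SoxB transcription factor (-3.64 ± 0.35), Irx3, a homeobox gene of the neural tube (-2.10 ± 0.15), and Nes, the intermediate filament nestin (-0.60 ± 0.06), while Lhx2 rose (0.70 ± 0.12). The mean log2 levels of this list, relative to the mean over the 8 libraries, were 1.28 and 1.36 in the Prdm16 control. They were -0.22 and -0.37 in its knockout and -0.25 and -0.03 in the PR domain control. The wild-type sets thus differed on this list too (median -1.25, camera adjusted p = 0.00298, adjusted p = 0.0813 with an estimated correlation). The size of the fall therefore depends on the control set. Genes of the primed epiblast and primitive streak fell in 12 of 17 cases and rose in 1, again with the same counts adjusted over the list alone. The list median was -1.58 (camera adjusted p = 2.39e-05). Otx2, a head and epiblast homeobox gene, fell from 285 ± 9.98 to 47.4 ± 4.85, and Dnmt3b, a de novo DNA methyltransferase, fell by 1.05 on the log2 scale. Cer1, a secreted Nodal and BMP antagonist, went from 88 fragments to 0, at least 25.7-fold lower against a floor of 3 fragments over the group. In the Notch pathway 12 of 17 members fell and 0 rose (14 and 1 adjusted over the list alone). Their median log2 fold change was -0.93 (camera adjusted p = 1.09e-05, adjusted p = 0.0641 with an estimated correlation). The ligands Jag1 and Jag2 fell by 1.38 and 1.29 on the log2 scale and the receptors Notch1 and Notch3 fell by 0.93 and 0.58.

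Immediate early genes, transcribed within minutes of stimulation, rose in 14 of 16 cases in the Prdm16 knockout (15 adjusted over the list alone). The median of the list was 1.13 (camera adjusted p = 7.25e-23). The AP-1 subunit gene Fos went from 1866 ± 45.9 to 4960 ± 23.4, and Egr1, Fosb and Jun rose by 1.22, 1.22 and 1.21 on the log2 scale. Macrophage and mast cell markers rose in 11 of 12 cases, over all loci and adjusted over the list alone. As a set they had a median of 1.09 (camera adjusted p = 1.62e-13). Csf1r, the receptor that macrophages need to survive, went from 485 ± 16.3 to 1102 ± 14.5, and the chemokine receptor gene Cx3cr1 rose by 1.23 on the log2 scale. Visceral and definitive endoderm genes rose in 17 of 28 cases and fell in 3 (18 and 3 adjusted over the list alone). The set median was 0.72 (camera adjusted p = 5.81e-12). Among them were Afp (1.37 ± 0.04), Rbp4 (1.15 ± 0.04) and Apoe (0.92 ± 0.04), which encode secreted carrier proteins. Fibroblast and mesenchymal matrix genes rose in 13 of 21 cases and fell in 4, as adjusted over the list alone. The median member was at 0.38 (camera adjusted p = 2.23e-06). Postn, a matrix protein gene, rose by 1.00 on the log2 scale, and Prrx1, a mesenchymal homeobox gene, fell by 2.19.

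Cardiac lists moved apart in the Prdm16 knockout. Cardiac progenitor genes rose in 11 of 18 cases and fell in 3, as adjusted over the list alone. The list median was 0.51 (camera adjusted p = 0.000526, adjusted p = 0.0641 with an estimated correlation). The transcription factor genes Gata4, Gata6 and Hand2 rose by 0.71, 0.68 and 0.64 on the log2 scale, and Isl1 fell by 1.49. Cardiomyocyte contraction genes fell in 14 of 24 cases and rose in 2, as adjusted over the list alone. Their median log2 fold change was -0.39 (camera adjusted p = 0.000526, adjusted p = 0.154 with an estimated correlation). The ventricular myosin light chain gene Myl2 fell from 396 ± 1.76 to 134 ± 16.3, the atrial one Myl7 by 0.74 on the log2 scale, and Tnni1 rose by 0.53. Endothelial genes fell in 10 of 20 cases and rose in 2 (11 and 3 adjusted over the list alone). The median of the list was -0.43 (camera adjusted p = 0.0163, adjusted p = 0.121 with an estimated correlation). Examples were Cdh5, the junctional VE-cadherin gene, at -1.05 ± 0.07. Erythroid genes rose in 10 of 18 cases and fell in 3 (12 and 3 adjusted over the list alone). As a set they had a median of 0.51 (camera adjusted p = 0.0123, adjusted p = 0.121 with an estimated correlation). The embryonic globin gene Hbb-bh1 rose by 1.15 on the log2 scale and its neighbour Hbb-y fell by 0.28.

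Of the remaining lists in the Prdm16 knockout, hypoxia and glycolysis genes rose in 16 of 24 cases and fell in 2, as adjusted over the list alone. The set median was 0.32 (camera adjusted p = 4.61e-07, adjusted p = 0.0567 with an estimated correlation). Examples were Ndrg1 at 1.51 ± 0.07. Interferon response genes rose in 12 of 24 cases and fell in 1, as adjusted over the list alone. The median member was at 0.56 (camera adjusted p = 0.00198, adjusted p = 0.0687 with an estimated correlation). Cell cycle genes fell in 13 of 26 cases and rose in 1 (15 and 1 adjusted over the list alone). The list median was -0.18 (camera adjusted p = 0.000526, adjusted p = 0.143 with an estimated correlation). Enzymes that add or remove methyl groups on histone H3K4 and H3K9, and their partners, fell in 15 of 28 cases and rose in 1 (15 and 2 adjusted over the list alone). Their median log2 fold change was -0.20 (camera adjusted p = 0.00316, adjusted p = 0.121 with an estimated correlation). Examples were Kmt2a, an H3K4 methyltransferase gene, at -0.54 ± 0.06. Neuronal genes fell in 9 of 14 cases and rose in 2 (10 and 2 adjusted over the list alone). The median of the list was -0.95 (camera adjusted p = 0.0440, adjusted p = 0.191 with an estimated correlation). The list did not pass without either Prdm16 control library or without knockout replicate 1 (adjusted p = 0.102). The other 19 lists did not pass.

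The single genes with the largest changes in the Prdm16 knockout were a small set. Cdhr2, a brush border protocadherin gene, rose from 42.2 ± 4.18 to 344 ± 14.5 (chromosome 13, 54701461 to 54736662), and the apolipoprotein genes Apoc1 and Apoa2 rose by 2.65 and 2.55 on the log2 scale. Grb10, an imprinted adaptor gene of insulin receptor signalling, fell from 3999 ± 185 to 36.6 ± 11.4 (chromosome 11, 11930508 to 12038683, -6.76 ± 0.10, limma adjusted p = 9.67e-30). The transcription factor genes Pax1 (170 ± 3.82 to 2.41 ± 1.85), Ebf2 (104 ± 1.06 to 2.96 ± 1.08) and Ebf1 (77.1 ± 4.05 to 10.7 ± 8.16) also fell. The 4 tested protein-coding genes on the Y chromosome were near 0 in both Prdm16 knockout libraries and at 64.7 or more normalised fragments in both control libraries. Ddx3y, Uty and Kdm5d were at 0 and at least 295-fold, 117-fold and 43.9-fold lower against a floor of 3 fragments over the group, and Eif2s3y had 1 fragment against 1023, or 0.111% of control (95% exact interval 0.00282 to 0.622%). Across the comparison, limma called 6502 loci (39.1% of 16623), 2987 higher and 3515 lower, of which 548 and 650 by 2-fold or more. The larger direction depended on scaling, with 45.9% of calls higher in the main test, 52.9% with DESeq2 median-ratio scaling, 55.0% with TMM and 39.3% with total-fragment scaling. DESeq2's Wald test called 3983 loci and a minimum fold of 1.5 left 683. On log2(FPKM + 1) the count was 1876, and Notch1, Myl7, Kmt2a, Ebf1 and Lhx2 kept their direction but did not pass.

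**Figure D2:**
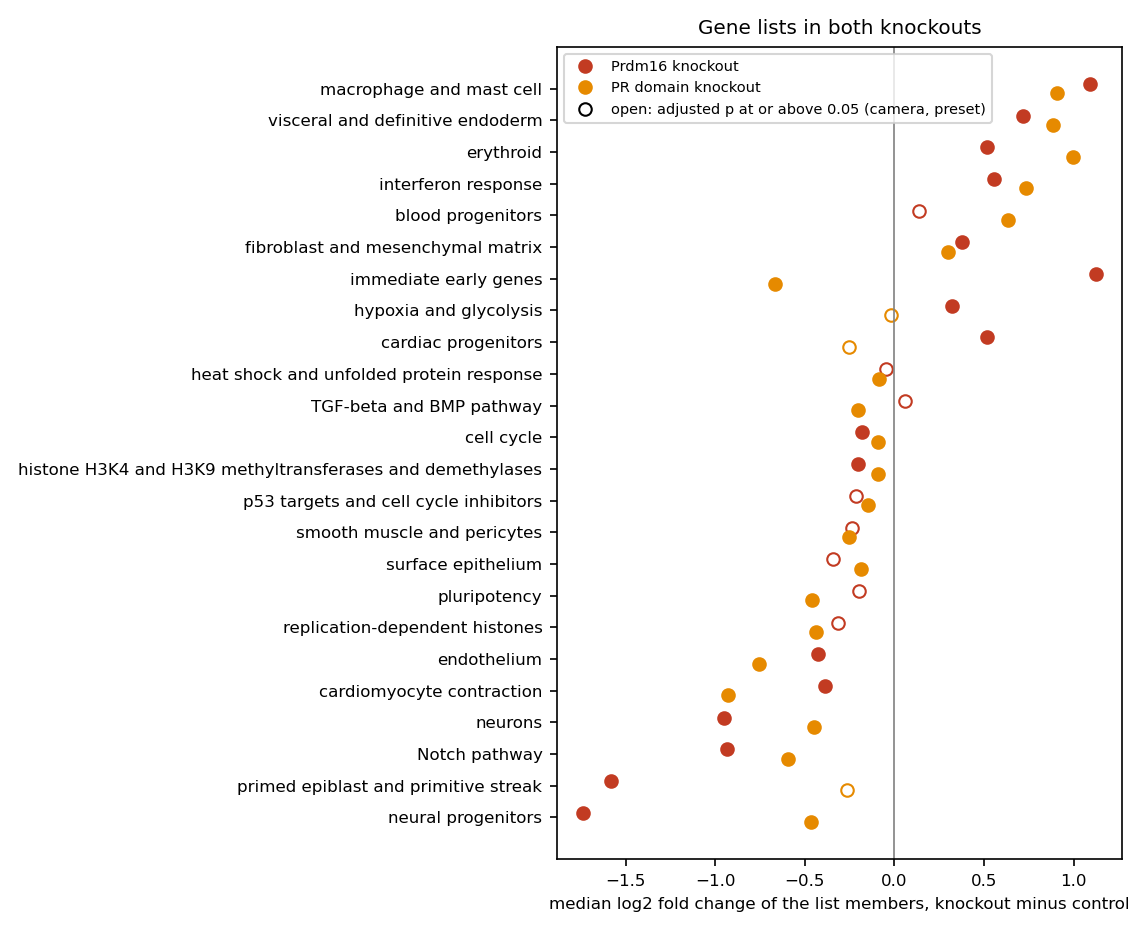
Median log2 fold change of the tested members of each gene list that passed in at least 1 knockout, for the Prdm16 knockout (red) and the PR domain knockout (orange), with open circles for an adjusted p at or above 0.05 (camera, preset correlation). Macrophage and mast cell genes had medians of 1.09 and 0.91, and immediate early genes had medians of 1.13 and -0.67.

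The second comparison asked which genes differed between the PR domain knockout and its control set. Cardiomyocyte, endothelial and immediate early genes fell in the PR domain knockout, and endoderm, macrophage, erythroid and interferon response genes rose. Cardiomyocyte contraction genes fell in 20 of 24 cases and rose in 1 (21 and 1 adjusted over the list alone). As a set they had a median of -0.93 (camera adjusted p = 9.67e-27). Actc1, cardiac actin, went from 4199 ± 213 to 1575 ± 119. The locus that joins the cardiac myosin heavy chain genes Myh6 and Myh7 went from 6291 ± 337 to 2201 ± 149, and Myl7 from 3444 ± 40.6 to 1407 ± 126. Endothelial genes fell in 16 of 20 cases and rose in 1 (18 and 1 adjusted over the list alone). The set median was -0.75 (camera adjusted p = 9.74e-13). Examples were Cdh5 at -1.35 ± 0.07, the receptor gene Tie1 at -0.90 ± 0.07 and the transcription factor gene Sox18 at -1.33 ± 0.18. In the Notch pathway 11 of 17 members fell and 1 rose (13 and 1 adjusted over the list alone). The median member was at -0.60 (camera adjusted p = 2.21e-06, adjusted p = 0.0526 with an estimated correlation). The endothelial ligand gene Dll4 fell from 127 ± 16.5 to 32.8 ± 1.88 (chromosome 2, 119325784 to 119335962), the receptor gene Notch4 by 1.87 on the log2 scale and the target gene Hey1 by 0.85. Immediate early genes fell in 15 of 16 cases, over all loci and adjusted over the list alone. The list median was -0.67 (camera adjusted p = 1.04e-24). Examples were Ier2 (-1.13 ± 0.06), Btg2 (-1.01 ± 0.05) and Fos (-0.64 ± 0.04).

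Endoderm genes rose in 21 of 28 cases and fell in 2 in the PR domain knockout (23 and 2 adjusted over the list alone). Their median log2 fold change was 0.88 (camera adjusted p = 1.32e-23). Apob, the structural protein of lipoprotein particles, went from 1307 ± 39.4 to 2963 ± 257, and Apoe and Rbp4 rose by 0.89 and 0.88 on the log2 scale. Macrophage and mast cell markers rose in 12 of 12 cases, over all loci and adjusted over the list alone. The median of the list was 0.91 (camera adjusted p = 1.27e-22). Examples were Csf1r at 1.02 ± 0.05 and the complement gene C1qb at 0.90 ± 0.08. Erythroid genes rose in 13 of 18 cases and fell in 0 (17 and 0 adjusted over the list alone). As a set they had a median of 1.00 (camera adjusted p = 6.08e-22). Alas2, which starts haem synthesis in red cells, rose by 1.21 on the log2 scale, and the embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y rose by 0.97, 0.95 and 0.93. Blood progenitor genes rose in 9 of 17 cases and fell in 3 (10 and 3 adjusted over the list alone). The set median was 0.63 (camera adjusted p = 0.00486, adjusted p = 0.0778 with an estimated correlation). Examples were the integrin gene Itga2b at 1.32 ± 0.07 and Cd34 at -0.71 ± 0.07. Interferon response genes rose in 17 of 24 cases, over all loci and adjusted over the list alone. The median member was at 0.73 (camera adjusted p = 1.69e-10). Fibroblast and matrix genes rose in 15 of 21 cases and fell in 3 (15 and 4 adjusted over the list alone). The list median was 0.30 (camera adjusted p = 3.90e-11). Examples were the collagen genes Col1a1 (0.62 ± 0.03) and Col1a2 (0.46 ± 0.03).

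Smooth muscle and pericyte genes fell in 7 of 13 cases and rose in 1 in the PR domain knockout (8 and 1 adjusted over the list alone). Their median log2 fold change was -0.25 (camera adjusted p = 0.000396, adjusted p = 0.0526 with an estimated correlation). Acta2, smooth muscle actin, went from 7529 ± 179 to 4147 ± 13.5, Myocd, a coactivator of muscle genes, fell by 1.64 on the log2 scale, and Mylk rose by 1.29. TGF-beta and BMP pathway genes fell in 13 of 28 cases and rose in 2 (14 and 2 adjusted over the list alone). The median of the list was -0.20 (camera adjusted p = 0.000585, adjusted p = 0.0667 with an estimated correlation). Examples were the BMP target genes Id1 and Id3 at -0.93 ± 0.07 and -0.91 ± 0.06. Neural progenitor genes fell in 6 of 19 cases and rose in 0, as adjusted over the list alone. As a set they had a median of -0.47 (camera adjusted p = 0.00128, adjusted p = 0.0598 with an estimated correlation). Examples were Irx3 at -1.14 ± 0.15. Cell cycle genes fell in 9 of 26 cases and rose in 0, as adjusted over the list alone. The set median was -0.09 (camera adjusted p = 0.00341, adjusted p = 0.177 with an estimated correlation).

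A further 7 lists passed at camera adjusted p between 0.0208 and 0.0465 in the PR domain knockout, all lower, and none held with an estimated correlation. Heat shock and unfolded protein genes fell in 6 of 19 cases and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation), replication-dependent histone genes in 2 of 8 (adjusted p = 0.186 with an estimated correlation), and p53 target genes in 7 of 21 with 1 higher (adjusted p = 0.177 with an estimated correlation). Histone H3K4 and H3K9 methylation enzymes fell in 3 of 28 cases (adjusted p = 0.186 with an estimated correlation), neuronal genes in 4 of 14 with 1 higher (adjusted p = 0.186 with an estimated correlation), pluripotency genes in 6 of 13 with 2 higher (7 and 2 adjusted over the list alone, adjusted p = 0.371 with an estimated correlation), and surface epithelium genes in 7 of 16 with 1 higher (adjusted p = 0.330 with an estimated correlation). For the histone, p53, methylation enzyme, neuronal and epithelium lists the counts adjusted over the list alone were the same. All but the heat shock list lost the call without 1 library, at adjusted p up to 0.1004 (histones), 0.103 (p53), 0.165 (pluripotency) and 0.169 (epithelium) without knockout replicate 1, and up to 0.167 (methylation enzymes) and 0.0859 (neurons) without knockout replicate 2. Leaving out 1 or the other PR domain control library ended these calls as well, and leaving out either Prdm16 control library ended those of the neuronal, pluripotency and epithelium lists. Tdgf1, a Nodal co-receptor gene of the epiblast, fell from 124 ± 3.71 to 28.6 ± 8.71. The other 14 lists did not pass.

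Single genes with the largest rises in the PR domain knockout included Itih2 (15.9 ± 5.26 to 77.2 ± 5.04, log2 fold change 2.24 ± 0.29, chromosome 2, 10094593 to 10131396), Apom (59.8 ± 10.1 to 215 ± 8.71), a lipocalin of lipoprotein particles, and the myeloid genes Il10ra (1.78 ± 0.24) and Ms4a7 (1.79 ± 0.41). The largest falls included Ebf2 (177 ± 37.6 to 34.3 ± 2.90), the homeobox gene Six2 (-2.10 ± 0.31) and Otx2 (-1.74 ± 0.19). The Y-linked genes were at 451.6 or more normalised fragments in both PR domain knockout libraries, and Ddx3y had a log2 fold change of 0.19 ± 0.12 (limma adjusted p = 0.325). Across the comparison, limma called 3190 loci (19.2%), 1410 higher and 1780 lower, of which 303 and 229 by 2-fold or more. Of the calls 44.2% were higher, against 54.4% with DESeq2 median-ratio scaling, and DESeq2's Wald test called 1794 loci. On log2(FPKM + 1) the count was 502, against a minimum fold of 1.5 it was 221, and Myl7, Notch4, Dll4 and Otx2 were among the genes that kept their direction and lost the call with at least 1 FPKM setting. Notch1, at -0.84 ± 0.09 in the main test, was at 0.0115 on log2(FPKM + 1).

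Both knockouts shared more calls than lists drawn independently would. Of the 2139 loci called in both, 1927 changed in 1 direction (90.1%), 903 higher in both where independent lists give 253, and 1024 lower in both where they give 376 (one-sided Fisher's exact test for the lower set, p = 3.85e-283, odds ratio 6.72). Opposite calls came to 144 loci higher in the Prdm16 knockout and lower in the PR domain knockout, and to 68 the other way. Fisher's test treats loci as independent, so its p-value does not measure the spread between libraries. The control libraries of the comparisons were separate. The log2 fold changes correlated across the 16623 loci at Pearson r = 0.421 and Spearman rho = 0.397, where loci are not independent replicates. Ebf2, Otx2 and Cdh5 were among the genes lower in both, and Csf1r, Apoe, Rbp4 and Hbb-bh1 among those higher in both. Of 35 lists tested, 16 passed in the Prdm16 knockout and 21 in the PR domain knockout, 13 passed in both and 12 of these moved in 1 direction. With an estimated correlation 6 and 8 lists held, in the Prdm16 knockout the immediate early, macrophage, endoderm, fibroblast, neural progenitor and primed epiblast lists (adjusted p = 0.0470 each with an estimated correlation), and in the PR domain knockout the cardiomyocyte, immediate early, endoderm, macrophage, erythroid, endothelial, fibroblast and interferon lists (adjusted p = 0.0104 each). Without the loci on chromosomes 8, 19 and Y, 1530 loci were called the same way in both, from 5803 and 2513 calls. The lists that passed then came to 17 and 19, as the cartilage and bone list passed in the Prdm16 knockout (camera adjusted p = 0.0413) and the pluripotency and surface epithelium lists did not in the PR domain knockout (camera adjusted p = 0.112 and 0.0792). DESeq2's Wald test gave 1063 such loci and log2(FPKM + 1) gave 258.

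**Figure D3:**
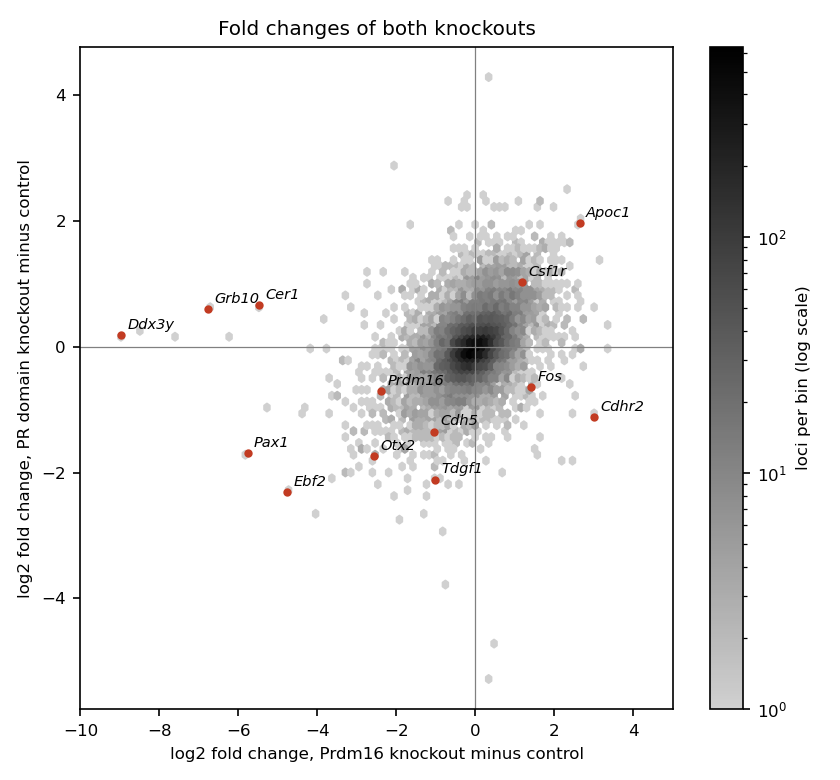
Log2 fold change of each tested locus in the Prdm16 knockout (horizontal axis) and the PR domain knockout (vertical axis), with grey bins shaded by the number of loci on a log scale and named genes as red points. Ebf2, Pax1 and Otx2 lie low on both axes, Fos and Cdhr2 lie high on 1 axis and low on the other, and the fitted position of Ddx3y and Cer1, at 0 fragments in the Prdm16 knockout, depends on the pseudocount.

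The third comparison tested whether the changes of both knockouts differed. Immediate early genes differed most as a group, with 15 of 16 members higher in the Prdm16 knockout relative to the PR domain knockout, over all loci and adjusted over the list alone. The median member was at 1.80 (camera adjusted p = 2.48e-51, adjusted p = 0.0198 with an estimated correlation). The differences were 2.05 ± 0.05 for Fos and 2.42 ± 0.18 for Arc, an immediate early gene of neurons. Cardiomyocyte contraction genes had 14 of 24 members with a higher and 1 with a lower change in the Prdm16 knockout (15 and 2 adjusted over the list alone). The list median was 0.58 (camera adjusted p = 1.80e-10, adjusted p = 0.0759 with an estimated correlation). Their mean levels, relative to the mean over the 8 libraries, differed between the Prdm16 control (-0.24 and -0.21) and the PR domain control (0.80 and 0.80). The Prdm16 knockout lay at -0.51 and -0.62, below the PR domain knockout at 0.003 and -0.02, so this difference depends on the control sets. Cardiac progenitor genes had 11 of 18 higher and 0 lower (13 and 1 adjusted over the list alone). Their median log2 fold change was 0.44 (camera adjusted p = 4.40e-08, adjusted p = 0.0559 with an estimated correlation). Hypoxia and glycolysis genes had 13 of 24 higher and 1 lower, as adjusted over the list alone. The median of the list was 0.31 (camera adjusted p = 3.93e-09, adjusted p = 0.0601 with an estimated correlation). Erythroid genes had 6 of 18 lower and 1 higher (10 and 2 adjusted over the list alone). As a set they had a median of -0.63 (camera adjusted p = 2.37e-06, adjusted p = 0.0601 with an estimated correlation). Primed epiblast genes had 8 of 17 lower and 0 higher, as adjusted over the list alone. The set median was -0.85 (camera adjusted p = 0.000724, adjusted p = 0.0760 with an estimated correlation). Their mean levels were high in the Prdm16 control (1.99 and 1.88) and low in the PR domain control (-0.87 and -0.79), so this difference depends on the control sets as well. A further 7 of the 13 lists that passed had camera adjusted p between 0.000724 and 0.0456, and none of the 7 held with an estimated correlation (adjusted p = 0.0760 to 0.149).

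Among the genes named by the rule, the largest negative differences were those of Grb10 (-7.36 ± 0.14) and the Y-linked genes, all lower in the Prdm16 knockout. The largest positive differences were those of Cdhr2 (4.12 ± 0.49) and Trap1a, an X-linked tumour rejection antigen gene (4.03 ± 0.55). Cdhr2 and Trap1a rose in the Prdm16 knockout and fell in the PR domain knockout, where their control levels were 7.13 and 5.62. Trap1a had 3 fragments in the PR domain knockout and 11 in its control, or 23.3% of control (95% exact interval 4.18 to 88.3%). Mecom differed by 0.64 ± 0.13 (limma adjusted p = 0.000547). Limma called 2728 loci for the difference, 1430 higher and 1298 lower (52.4% higher), and with total-fragment scaling 37.0% were higher. On log2(FPKM + 1) 170 loci passed, with 62.9% higher, 169 passed against a minimum fold of 1.5, 1189 passed with DESeq2's Wald test and 1642 without a low-count filter.

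**Figure D4:**
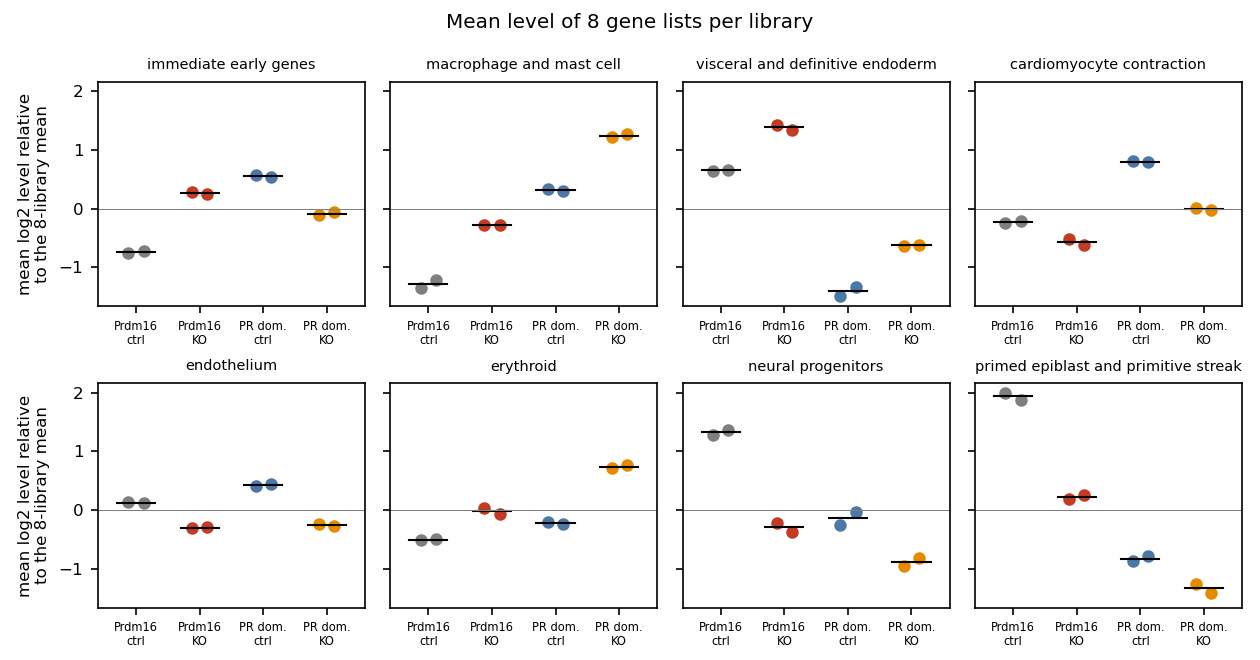
Mean log2 level of the tested members of 8 gene lists in each library (points), relative to the mean over the 8 libraries, with the group means as lines. Immediate early genes rise from control to knockout in the Prdm16 set and fall in the PR domain set, and endoderm and primed epiblast genes are highest in the Prdm16 set.

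The fourth comparison set both wild-type control sets against each other, which measures differences that no knockout made. The PR domain control expressed more cardiomyocyte, macrophage and immediate early genes and less of the endoderm and epiblast genes than the Prdm16 control. Endoderm genes were lower in 22 of 28 cases and higher in 0, as adjusted over the list alone. The median member was at -1.99 (camera adjusted p = 8.00e-32). Pga5, a pepsinogen gene, had 434 fragments in the Prdm16 control and 0 in the PR domain control, at least 142-fold lower against a floor of 3 fragments over the group, and Amn, an endocytic receptor gene of visceral endoderm, went from 156 ± 7.55 to 2.06 ± 2.92. Primed epiblast genes were lower in 15 of 17 cases (16 adjusted over the list alone). Over the list the median was -2.91 (camera adjusted p = 1.16e-13). Cardiomyocyte contraction genes were higher in 20 of 24 cases (22 adjusted over the list alone, median 1.09, camera adjusted p = 1.89e-23). Immediate early genes were higher in 15 of 16 (median 1.30, camera adjusted p = 7.68e-30) and macrophage markers in 12 of 12 (median 1.51, camera adjusted p = 7.45e-22), these last 2 with the same counts adjusted over the list alone. The cytokine gene Il1b differed from 7.59 ± 2.76 to 71.0 ± 12.9, and the locus joining the lysozyme genes Lyz1 and Lyz2 from 148 ± 5.11 to 885 ± 16.5. Of the Y-linked genes, Kdm5d was higher by 2.67 ± 0.19 and Ddx3y by 1.01 ± 0.12. Limma called 5481 loci (33.0%), 2710 higher and 2771 lower (49.4% higher, and 54.3% with TMM scaling), and 19 lists passed, 7 of them also with an estimated correlation. The first principal component held 59.0% of the variance and separated the Prdm16 set from the PR domain set, and the second held 25.9% and separated knockout from control within each set. DESeq2's Wald test called 3388 loci. On log2(FPKM + 1) the count was 1517, and against a minimum fold of 1.5 it was 761.

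Loci on chromosomes 8 and 19 were lower as sets in both knockouts. Relative to the other autosomes, the median of 622 chromosome 8 loci was -0.16 in the Prdm16 knockout and -0.31 in the PR domain knockout, where 89.2% of them lay below the median of the other autosomes. For 412 chromosome 19 loci the medians were -0.19 and -0.11. In the PR domain control against the Prdm16 control, which no knockout separates, the medians were 0.20 on chromosome 8 and 0.08 on chromosome 19. Each was outside the range of 2000 random lists of the same size. Such lists treat loci as independent, and shifts on other chromosomes were outside their range as well. Chromosome 6 had medians of 0.12 in the PR domain knockout and -0.12 between the control sets. Both were larger in size than those of chromosome 19 and opposite in sign. Smaller examples were 0.029 on chromosome 11 in the PR domain knockout and -0.067 on chromosome 17 between the control sets. Chromosome 8 held 5.67 and 5.70% of the fragments of the PR domain control libraries, 4.55 and 4.61% in that knockout, 4.98 and 4.98% in the Prdm16 control and 4.41 and 4.35% in the Prdm16 knockout. Cdh5, Hand2, Irx3 and Ier2 lie on chromosome 8, and Acta2, Rbp4, Ms4a7 and Pga5 lie on chromosome 19.

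**Figure D5:**
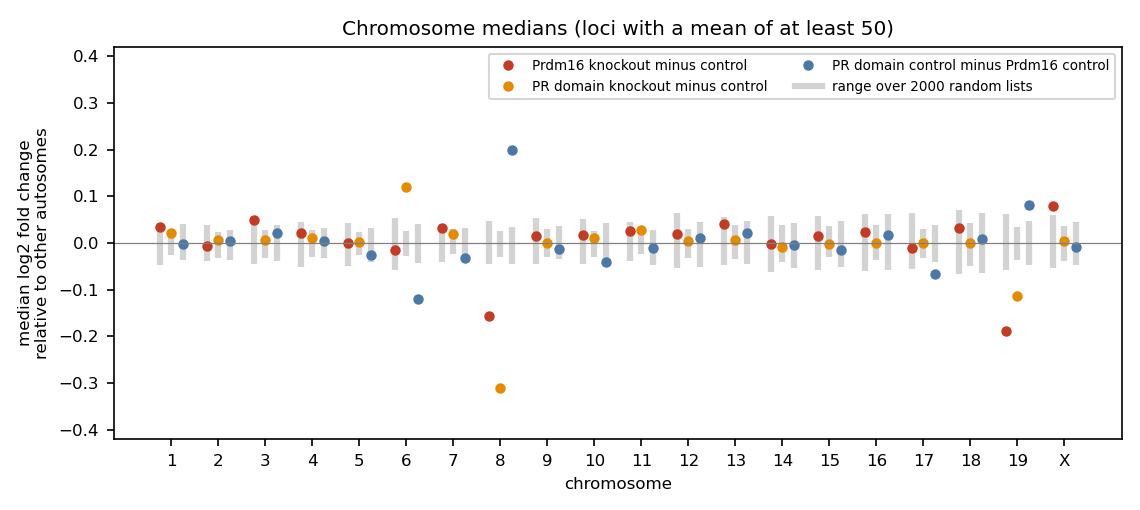
Median log2 fold change of the loci on each chromosome relative to the other autosomes, for loci with a mean of at least 50, with grey bars for the range over 2000 random lists of the same size. Chromosome 8 lies at -0.16 and -0.31 and chromosome 19 at -0.19 and -0.11 in the Prdm16 and PR domain knockouts, and chromosome 6 at 0.12 in the PR domain knockout.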

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

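The tests of Y chromosome absence, of Xist, of exchanged libraries and of the macrophage list were chosen only after the result was seen, and the chromosome part, GC content and heat shock tests were set before.

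Loci on chromosomes 8 and 19 were lower as sets in both knockouts than in their controls. GC content bias is argued against: after the GC trend was removed the chromosome 8 medians were -0.15 in the Prdm16 knockout and -0.31 in the PR domain knockout, and the chromosome 19 medians -0.18 and -0.11. A lower number of copies of the whole chromosome in the knockout cells, relative to their control cells, is a candidate explanation. The medians of 4 parts of chromosome 8 with like numbers of loci were below 0 in both knockouts (highest -0.103). Those of chromosome 19 were too (highest -0.0825). These parts hold the same loci that showed the pattern. They show that the shift spans each chromosome, and cannot separate a number of copies from a response in transcription. Whether control cells gained or knockout cells lost copies was not tested, and the wild-type control sets differed on the same chromosomes, with medians of 0.20 on chromosome 8 and 0.08 on chromosome 19 for the PR domain control against the Prdm16 control. A response of these chromosomes to the loss of Prdm16 was not tested and stays open.

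Y-linked genes were near 0 in both Prdm16 knockout libraries. Knockout bodies made from XX cells with X inactivation are argued against by Xist, which was at most 3.30 in the Prdm16 knockout libraries. An exchange of both knockout libraries with both control libraries cannot be told apart from correct labels by Ddx3y. Prdm16 itself had a log2 fold change of -2.38 ± 0.50, the direction the labels call for. It stayed negative under every setting (-1.11 to -3.65 with 1 library left out, each a call, and -1.98 on log2(FPKM + 0.1) and -0.69 on log2(FPKM + 1), neither a call). What keeps the exchange open is that this is 1 low gene and that the part removed is not given in the sources used here, so the fragments a knockout leaves are not known. Absence of the whole Y chromosome from the knockout cells cannot be told apart from the loss or silence of 1 part of it. The tested Y-linked loci lie between 897788 and 1286629, and outside that part the Y-linked loci that are no pseudogenes had 0 fragments in the Prdm16 control. The 3 pseudogenes with fragments there held 5 in the knockout and 18 in the control, and were set aside because such fragments can come from the parent genes on other chromosomes. Whether this came with the knockout, with the cell clone or with the line of origin stays open, because knockout and clone cannot be separated with 1 knockout set.

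Immediate early genes rose in the Prdm16 knockout and fell in the PR domain knockout, a median difference of 1.80 by the test of the difference itself. The wild-type sets differed too, with a median 1.30 higher in the PR domain control than in the Prdm16 control, while the knockout libraries lay closer together (mean levels of 0.28 and 0.26 in the Prdm16 knockout and -0.11 and -0.06 in the PR domain knockout, relative to the mean over the 8 libraries), so much of the difference lies between the control sets. A different share of macrophages and mast cells is argued against in the PR domain knockout only. There that list rose (median 0.91) while the immediate early genes fell. In the Prdm16 knockout and between the control sets the list moved with the immediate early genes (medians 1.09 and 1.51). For those comparisons this explanation cannot be told apart from others. A general stress response at harvest cannot be told apart from other causes: the heat shock and unfolded protein list had a median of -0.0478 in the Prdm16 knockout and -0.0858 in the PR domain knockout, with members moving both ways. By the test of the difference it went with the immediate early genes, with 8 of 19 members higher in the Prdm16 knockout relative to the PR domain knockout and 2 lower (8 and 3 adjusted over the list alone, median 0.27, camera adjusted p = 0.00223, adjusted p = 0.0760 with an estimated correlation). Handling time at harvest is not given in the sources used here, and an effect of Prdm16 itself was not tested apart from it.

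Other immediate early genes with opposite calls and a called difference were Fos (difference in log2 fold change 2.05), Fosb (1.97), Egr1 (1.66), Jun (1.52), Ier2 (1.69), Btg2 (2.03), Arc (2.42) and the stress-responsive gene Atf3 (2.12). Opposite calls with a called difference were also found for Acta2 (1.04), Hand2 (0.98), Tnni1 (0.67), Id2 (0.69), Cdhr2 (4.12) and Trap1a (4.03), which were higher in the Prdm16 knockout, and for Asns (-0.78), Car2 (-1.79), Hbb-y (-1.21), Grb10 (-7.36) and Pga5 (-4.97), which were lower there. The value for Pga5 depends on the pseudocount, since it had 16 fragments in the PR domain knockout and 0 in its control, at least 4.56-fold higher against a floor of 3 fragments over the group. Among 449 tested loci without a gene name, which no comparison used, 11 were higher and 30 lower in the Prdm16 knockout than in its control, and 1 was higher and 1 lower in the PR domain knockout.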

How the results depend on the processing

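The edgeR test, TMM scaling, pseudocounts of 0.5 and 5, the crossed pairing and the run without chromosomes 8, 19 and Y were chosen only after the data were seen. Of 204 gene results that passed, 105 stayed past the threshold in the same direction under every setting tried on them. Of 37 list results, 14 did so under the settings tried on lists, which were fewer. Some of both lost the call when 1 library was left out. Lists were not tried with the FPKM settings, DESeq2's Wald test, limma-voom, edgeR, total-fragment scaling or upper-quartile scaling. Nor were they tried with the CPM filter, only the libraries compared, the most abundant loci left out, a minimum fold or the crossed pairing. The list and gene figures therefore cannot be compared. DESeq2's Wald test gave 3983 loci in the Prdm16 knockout, 1794 in the PR domain knockout, 1189 for their difference, 3388 between controls and 1063 shared. With log2(FPKM + 1) these were 1876, 502, 170, 1517 and 258, with log2(FPKM + 0.1) 1844, 439, 146, 1511 and 229, and with log2(FPKM + 1) and no filter 1426, 346, 170, 1186 and 154. A minimum fold of 1.5 gave 683, 221, 169 and 761, and no low-count filter 1642 for the difference. With an estimated correlation 6 lists held in the Prdm16 knockout and 8 in the PR domain knockout, and fry gave 26 in the Prdm16 knockout. Prdm16 in the Prdm16 knockout was -0.69, -1.98 and -0.69 with the FPKM settings and did not pass. With these 3 settings Kdm5c in PR domain knockout was 0.0189, 0.0193 and 0.0189, and Notch1 in PR domain knockout 0.0115, 0.0204 and 0.0115, both negative otherwise; the cause was not tested, as for the other changes, apart from the minimum fold, which tests less by construction.

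With 1 library left out the counts ranged from 5028 to 6477 in the Prdm16 knockout, 2180 to 3367 in the PR domain knockout, 1950 to 2390 for the difference, 4047 to 5675 between controls and 1361 to 1810 shared, Prdm16 from -3.65 to -1.11 and from -1.18 to -0.23, and lists from 15 to 17 and from 16 to 23. Same-numbered libraries did not deviate together (correlation -0.127 in the Prdm16 sets and 0.0117 in the PR domain sets). The first was past the limit of -0.1 for a crossed pairing. Both knockout sets correlated with each other at -0.176 and both control sets at 0.0093. No pairing by number was seen, which does not show that libraries were handled apart. A replicate block nested in the set gave 6501, 3210, 2719 and 5516 loci, 1950 shared, and a shared block 6438, 3149, 2686 and 5442. Crossed pairing gave 6387 in the Prdm16 knockout. Low genes such as Prdm16, at 1 to 44 fragments, are limited by depth.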

Other observations

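The chromosome 6 median and the neighbours of Grb10 were looked at only after the fold changes had been seen, and no explanation was tested for either.

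Other gene groups differed between the control sets. Smooth muscle and pericyte genes were higher in the PR domain control in 8 of 13 cases and lower in 0 (9 and 0 adjusted over the list alone, median 0.83, camera adjusted p = 6.22e-07, adjusted p = 0.0254 with an estimated correlation), and fibroblast genes in 17 of 21 with 1 lower (18 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 2.25e-17, adjusted p = 0.0118 with an estimated correlation). Cell cycle genes were lower in 20 of 26 cases (21 adjusted over the list alone, median -0.26, camera adjusted p = 1.88e-07, adjusted p = 0.0699 with an estimated correlation). Esr1, the oestrogen receptor gene, went from 441 ± 17.6 in the Prdm16 control to 12.3 ± 2.74 in the PR domain control.

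The fall of Grb10 in the Prdm16 knockout was not shared by its neighbours within 1 Mb. Ddc, the next gene, had a log2 fold change of 0.43, Ikzf1 0.74, Fignl1 0.07 and Cobl 0.16. The low genes Vwc2 and Zpbp, at control means of 7.94 and 5.53, had 1.26 and 0.70. The list of imprinted genes as a whole had 12 of 28 members higher and 12 lower in the Prdm16 knockout (13 and 12 adjusted over the list alone). It did not pass (camera adjusted p = 0.333), but camera tests for a shift in 1 direction, which members moving both ways do not give. Only 4 of the 28 members were not called, while 39.1% of all tested loci were called. Whether imprinted genes were called more often than genes of like level was not tested. Loci on chromosome 6 had a median of 0.12 in the PR domain knockout and -0.12 in the PR domain control against the Prdm16 control, and loci on the X chromosome a median of 0.08 in the Prdm16 knockout, each outside the range of 2000 random lists.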
